A study of Homo sapiens with 6 samples.

How the data were processed

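Poly-A selected, stranded mRNA libraries were made from 100 ng of RNA per sample, per the labels' protocols. HepaRG cells of passages 15 to 18 were grown for 14 days, differentiated for 14 days and kept in basal medium for 5 days before the treatment of 72 h, per the labels. The submitters' processing notes name STAR 2.5.2, featureCounts, Subread 1.5.1 and the genome build GRCh38. The strand setting of the counting is not given in the sources used here, so reads of overlapping antisense genes may not be separated.

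The authors deposited 1 table of FPKM values with 3 decimals for 58037 gene rows and 6 libraries, and, per the file headers, each gene's identifier, symbol, type, position, strand and length. FPKM divides a gene's fragments by its length and by the library's total, so a gene's value depends on the share taken by all other genes. In each library the FPKM times the gene length were whole multiples of 1 step: 100% of the values printed finely enough to tell came out whole (tolerance 0.02 reads beyond rounding), and the sum of the resulting reads came within 1 read of the base of the FPKM scale. Depth is therefore known, at 8.96, 6.33 and 11.82 M reads for control replicates 1, 2 and 3 and 8.36, 14.36 and 15.94 M for fatty acid replicates 1, 2 and 3. No pair of libraries of a group agreed within sampling noise. Correlations of log2 values were 0.969 to 0.978 within the control group, 0.985 to 0.986 within the fatty acid group and 0.962 to 0.98 between groups.

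Groups and replicate numbers were taken from the sample titles. The comparison was fatty acid against control with all 6 libraries and no covariate. Genes with a mean of at least 0.5 FPKM were tested with limma 3.58.1 in R 4.3.3 (moderated linear model with an intensity trend) on log2(FPKM + 0.5), with Benjamini-Hochberg adjustment and a threshold of 0.05. The design fixed before the data were examined gave a count model for the case that the table held counts; since the table holds FPKM, the limma test was used. A p given after a gene in the text is the limma adjusted p. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 25 sets with 5 or more tested members, the union of the 5 drug metabolism lists being 1 of them. The 25 lists cover cytochrome P450, other phase I, phase II, uptake and efflux transport, nuclear receptors and transcription factors, fatty acid oxidation, PPAR targets, lipid droplets, fatty acid synthesis, cholesterol synthesis, bile acids, lipoproteins, glucose, endoplasmic reticulum stress, oxidative stress, inflammation, interferon, cell cycle, extracellular matrix, mitochondrially encoded genes, and hepatocyte, biliary, mesenchymal, and immune and endothelial markers. They were fixed before the data were examined, as was the panel of 24 genes. Named genes were all panel genes, the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 FPKM groups that did not overlap and a symbol that is not a clone or pseudogene name, and for each list up to 4 called members with the smallest adjusted p, or the 2 with the smallest p where none passed. Genes named outside this rule were chosen after their values were seen: ACSL1, AKR1C1, CYP1B1, CYP8B1, ETNK2, FGB, HADHB, MGST1, NNMT, SAA1 and SLC16A1 in the report, and all genes named with the further lists, as well as LIPE and IL1B. Some genes that the rule names are not reported here, though the counts include them.

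The gene test and the list test were tested on simulated data drawn from the real libraries' means and depths. Of genes changed 1.5-fold, 2-fold and 4-fold, 53.7%, 80.6% and 97% were called among 14702 genes, and 9.9% of the 171 calls were genes that had not been changed, above the 0.05 that the threshold aims at. With no gene changed there were 0 gene calls and 0 list calls, and a list lowered to 0.7 of its level was called. Genes were drawn independently with a shared dispersion (0.00295), so the simulation holds no correlation between genes. It therefore does not show how the list test behaves for correlated lists. The estimated correlation of the mitochondrially encoded list in the real data was 0.789.

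Alternatives planned before the data were examined were pseudocounts of 0.1 and 1, no expression filter and a minimum of 2 FPKM, scaling by the median of ratios, quantile normalization, rescaling to TPM, limma without the trend, the replicate number as a block, each library left out in turn, a bound on the fold change, camera with an estimated correlation, fry, and an exact permutation test of the panel. Alternatives added after seeing the data were limma voom on the recovered reads, scaling to the reads of nuclear genes, leaving out genes under 200 bases and thinning every library to the shallowest. Intervals of read ratios are exact conditional binomial intervals at 95%, with a floor of 3 reads over a group. Figures were drawn with matplotlib 3.10.9, and reads were recovered with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. The 45 rows of the Y copy of the pseudoautosomal region were not used in the lists.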

Results

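HepaRG is a human hepatic cell line that differentiates in culture into a mixture of hepatocyte-like and biliary-like cells, and is used to study drug metabolism because it keeps many liver enzymes. The data cover 6 poly-A RNA-seq libraries, 1 per sample of differentiated cells. In 3 samples the medium carried a mixture of palmitate and oleate (1 part to 2 parts, 0.5 mM in total, bound to albumin) for 72 h, and 3 control samples received 0.02% albumin alone. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The question named in the series title and design is how fatty acid loading, a model of steatosis, alters drug-metabolizing enzymes and transporters. Expression was read from the authors' deposited table of FPKM values (fragments per kilobase of gene and per M assigned reads). The reads behind the values came to 8.96, 6.33 and 11.82 M in control replicates 1, 2 and 3, and to 8.36, 14.36 and 15.94 M in fatty acid replicates 1, 2 and 3. Values below are mean FPKM ± SD with n = 3 per group, and log2 fold changes (fatty acid minus control, ± SE) are those of log2(FPKM + 0.5), which understates the change of low genes. Coordinates are in GRCh38.

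Fatty acid loading raised inflammation genes and several PPAR targets, and lowered many hepatocyte genes, drug-metabolizing enzymes among them. Of 14661 genes tested, 1891 passed the threshold, 1205 higher and 686 lower. The larger changes went mostly the other way, since 98 of the calls with an absolute log2 fold change of at least 1 were lower and 39 were higher. Among the 8 largest rises were TNFAIP6, a secreted hyaluronan-binding protein induced by TNF (chromosome 2, 151357592 to 151380048), from 0.726 ± 0.228 to 4.80 ± 0.736 FPKM, and ANGPTL4, a lipoprotein lipase inhibitor (chromosome 19, 8363289 to 8374373), from 6.19 ± 0.784 to 25.01 ± 1.44 FPKM. FABP4, a fatty acid-binding protein (chromosome 8, 81478419 to 81483263), rose from 17.1 ± 4.47 to 62.1 ± 5.96 FPKM, and the apolipoprotein gene APOA4 (chromosome 11, 116820700 to 116823306) from 6.15 ± 0.652 to 22.5 ± 1.71 FPKM. PTX3, a secreted pattern recognition protein (chromosome 3, 157436789 to 157443628), PDK4 (chromosome 7, 95583499 to 95596491) and LCN2, which encodes a siderophore-binding protein (chromosome 9, 128149071 to 128153455), were also in this group, with log2 fold changes of 1.66 ± 0.09, 1.57 ± 0.07 and 1.53 ± 0.12. Among the 8 largest falls were CYP1A2 (chromosome 15, 74748844 to 74756202), from 3.35 ± 0.316 to 0.361 ± 0.118 FPKM, and its neighbour CYP1A1 (chromosome 15, 74719542 to 74725610), from 8.82 ± 0.245 to 1.67 ± 0.182 FPKM. THRSP, a regulator of lipogenesis (chromosome 11, 78063861 to 78068351), fell from 6.29 ± 0.859 to 1.09 ± 0.153 FPKM. CYP7A1, the rate-limiting enzyme of classical bile acid synthesis (chromosome 8, 58490178 to 58500236), fell from 3.25 ± 0.798 to 0.498 ± 0.0535 FPKM. The limma adjusted p (Benjamini-Hochberg) of these 11 genes ran from 7.82e-05 for CYP1A1 to 0.00123 for FABP4.

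Another 3 genes among the largest changes were very short RNAs resting on few reads. MT-TN, a mitochondrial tRNA gene (positions 5657 to 5729 of the mitochondrial genome), had 1 read in the control libraries and 8 in the fatty acid libraries, a depth-adjusted ratio of 5.61 with a 95% exact interval of 0.752 to 249. SNORD46, a small nucleolar RNA gene (chromosome 1, 44776490 to 44776593), had 14 and 3 reads, 6.65-fold lower with fatty acid (interval 1.86 to 36.1), and MIR6772, a microRNA gene (chromosome 16, 57772289 to 57772352), had 7 and 0 reads, at least 3.33-fold lower with the floor set at 3 reads over the group (exact lower limit 2.06). The limma adjusted p was 0.0317 for MT-TN, 0.0217 for SNORD46 and 0.000316 for MIR6772. The intervals cover counting error only. MIR6772 was not called after thinning to the shallowest library (0.136). The call of MT-TN was lost without any 1 of control replicates 1 and 2 and fatty acid replicates 1, 2 and 3 (adjusted p 0.0695, 0.068, 0.119, 0.0737 and 0.0751), and that of SNORD46 without control replicate 2 or 3 or fatty acid replicate 1 or 2 (0.0509, 0.0531, 0.0847 and 0.0821). With no filter neither was called (0.095 and 0.0702), and MT-TN was not called without the intensity trend (0.0604) or with voom on recovered reads (0.202).

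Every one of the 1891 called genes had groups that did not overlap. Over all tested genes 5433, or 37.1%, had such groups, where chance gives 10% for 3 against 3. The first principal component held 40.5% of the variance and separated the 2 groups. Mitochondrially encoded genes took 13.63 ± 1.37% of the reads in the control libraries and 10.31 ± 1.43% in the fatty acid libraries. The split of calls depended on the scaling. The median log2 fold change of all genes was 0.04 as deposited. Scaling to the median of ratios gave 717 higher and 861 lower genes, quantile normalization 758 and 772, and scaling to nuclear reads 706 and 828, whereas rescaling to TPM moved the median of all genes to 0.18 and gave 2615 and 408. The number of calls was 463, 484 and 913 without fatty acid replicate 1, 2 or 3, and 1041 without control replicate 3.

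**Figure D1:**
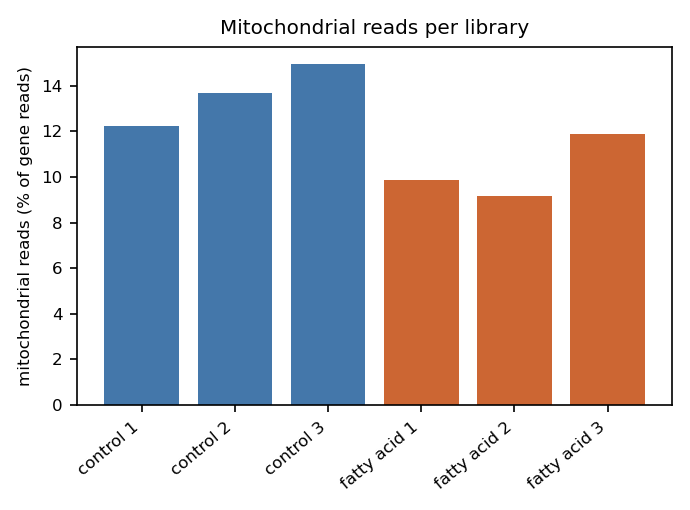
Bars give the percentage of each library's gene reads that fell on mitochondrially encoded genes, in 3 control and 3 fatty acid libraries. The control libraries lie between 12.23% and 14.96% and the fatty acid libraries between 9.15% and 11.91%.

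Drug metabolism and transport was the subject of the study, and of its genes past the threshold more fell than rose. Of 172 genes in the 5 lists fixed for it, 124 were expressed highly enough to be tested. Of these, 62 fell and 6 rose, and adjusted over the list alone 72 were lower and 11 higher. The genes of the 5 lists were lower than other genes as a set (camera adjusted p = 6.97e-21, and adjusted p = 0.034 with an estimated correlation). Hepatocyte marker genes fell alongside them, 17 of 24. The number of calls was 42 without fatty acid replicate 1 and 44 without fatty acid replicate 2, in place of 68. Set calls at the preset correlation also arose in other splits of the 6 libraries into 3 and 3, up to 12 lists against 19 in the real split. Those splits mix both groups unevenly on each side, so part of the treatment difference stays in them and their calls need not be false.

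Cytochrome P450 genes showed the largest falls of the 5 lists. Of 13 tested genes, 11 fell, 1 rose and 1 did not pass (the same counts adjusted over the list alone), with a median log2 fold change of -1.05. Besides CYP1A1 and CYP1A2, CYP2A6, the main nicotine oxidase, fell from 3.14 ± 0.311 to 0.516 ± 0.0427 FPKM and CYP2C8 from 35.2 ± 3.67 to 13.04 ± 0.801 FPKM (both limma adjusted p = 0.000176). CYP3A4, which metabolizes more marketed drugs than any other P450 enzyme, fell from 3.22 ± 1.22 to 0.931 ± 0.0634 FPKM (limma adjusted p = 0.0102), and CYP2B6 from 1.16 ± 0.179 to 0.300 ± 0.0425 FPKM (limma adjusted p = 0.00815). CYP1B1 was the gene that rose, from 12.3 ± 0.532 to 17.0 ± 0.839 FPKM (limma adjusted p = 0.00537). The set was lower than other genes (camera adjusted p = 1.75e-12, and adjusted p = 0.034 with an estimated correlation). Members of the CYP2C and CYP3A families are similar in sequence and may share reads, so their values are uncertain to that extent. The falling genes numbered 7 without fatty acid replicate 2, when CYP3A4 had an adjusted p of 0.0504.

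Other phase I enzymes fell in part. Of 42 tested genes, 18 fell, 1 rose and 23 did not pass, and adjusted over the list alone 22 were lower and 5 higher. The alcohol dehydrogenases led: ADH1C fell from 23.1 ± 2.47 to 6.07 ± 0.482 FPKM (limma adjusted p = 8.74e-05), ADH4 from 50.9 ± 5.76 to 16.1 ± 1.40 FPKM (0.000151) and ADH1B from 64.7 ± 7.08 to 24.4 ± 1.67 FPKM (0.000176). AKR1C4, an aldo-keto reductase that also acts in bile acid synthesis, fell from 16.8 ± 1.58 to 5.88 ± 0.530 FPKM (0.000176), while AKR1C1 rose from 36.9 ± 2.30 to 45.9 ± 1.12 FPKM (0.0183). The set test gave a camera adjusted p of 1.69e-09, which was lost with an estimated correlation (adjusted p = 0.0984). The ADH1 and AKR1C genes are near-identical families whose reads may be divided between members, and no gene of the list rose past the threshold without fatty acid replicate 1, 2 or 3. After rescaling to TPM 4 rose.

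Of 37 phase II conjugation enzyme genes tested, 22 fell, 2 rose and 13 did not pass, and adjusted over the list alone 22 were lower and 3 higher. GLYAT, the glycine N-acyltransferase, fell from 6.83 ± 0.315 to 1.66 ± 0.229 FPKM (limma adjusted p = 0.000131). Among the glucuronosyltransferases, UGT2B10 fell from 9.60 ± 0.764 to 2.36 ± 0.342 FPKM (0.00014), UGT2B15 from 53.8 ± 1.57 to 28.6 ± 0.942 FPKM (0.000135), UGT2B4 from 148.9 ± 2.78 to 89.9 ± 1.24 FPKM (0.000159) and UGT1A1, which conjugates bilirubin, from 19.5 ± 1.84 to 9.86 ± 0.628 FPKM (0.000677). The risers were NNMT and MGST1, with log2 fold changes of 0.35 ± 0.05 and 0.21 ± 0.05 (0.00558 and 0.0474). The set was lower than other genes (camera adjusted p = 7.59e-13, and adjusted p = 0.0206 with an estimated correlation). UGT1A genes share their last exons, so reads cannot be assigned to 1 of them with certainty. The falling genes numbered 14 without fatty acid replicate 1 or 2, and 1 gene rose without control replicate 3 or any 1 fatty acid replicate.

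Of 15 uptake transporter genes tested, 5 fell and 1 rose, and adjusted over the list alone 9 were lower and 1 higher. Among the falls were the organic anion transporter gene SLC22A7, from 3.73 ± 0.826 to 1.13 ± 0.185 FPKM (limma adjusted p = 0.00275), SLCO2B1, from 4.15 ± 0.855 to 1.51 ± 0.154 FPKM (0.00311), and SLC10A1, which encodes the bile acid importer NTCP, from 2.00 ± 0.274 to 0.647 ± 0.18 FPKM (0.00617). The monocarboxylate transporter gene SLC16A1 rose from 11.3 ± 0.512 to 14.9 ± 0.704 FPKM (0.011). Of 17 efflux transporter genes, 6 fell and 1 rose, and adjusted over the list alone 7 were lower and 1 higher. ABCC6 fell from 4.70 ± 0.503 to 2.81 ± 0.166 FPKM (0.00691) and ABCC11 from 1.48 ± 0.164 to 0.580 ± 0.0425 FPKM (0.00807), whereas ABCC4, an exporter of bile acids and cyclic nucleotides, rose from 2.83 ± 0.227 to 4.23 ± 0.285 FPKM (0.0135). The sterol exporter gene ABCG8 had 7.33 ± 2.10 and 3.80 ± 0.273 FPKM (0.0243). Both set tests passed with camera (adjusted p = 0.000101 for uptake and 0.00209 for efflux) and not with an estimated correlation (adjusted p = 0.0903 and 0.0882). Without control replicate 2 the uptake genes that fell numbered 9 and those that rose 2, and none rose without fatty acid replicate 1 or 2. The falling efflux genes numbered 2, 2, 3 and 2 without control replicate 3 and fatty acid replicates 1, 2 and 3, when ABCG8 was not called (adjusted p 0.0612, 0.098, 0.0948 and 0.0576). ABCG8 was not called with no filter (0.0724) or without the intensity trend (0.0511) either, and ABCC4 was not called without fatty acid replicate 1 or 2 (0.067 and 0.07). With no filter the falling efflux genes numbered 2.

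Few of the tested nuclear receptors and liver transcription factors passed the threshold. Of 37 tested genes, 3 fell and 1 rose, with 4 lower and 3 higher adjusted over the list alone. NR1I2, which encodes the xenobiotic receptor PXR, fell from 4.44 ± 0.259 to 2.10 ± 0.303 FPKM (limma adjusted p = 0.0022). HNF4A, a master regulator of hepatocyte genes, fell from 16.7 ± 1.36 to 11.7 ± 0.715 FPKM (0.00923), and the clock repressor gene NR1D1 from 10.3 ± 0.345 to 7.35 ± 0.626 FPKM (0.0104). NR5A2 had 2.13 ± 0.472 and 3.34 ± 0.111 FPKM (0.038). The set did not pass (camera adjusted p = 0.0708), though it did without control replicate 2 (0.0452), without fatty acid replicate 3 (0.0309), with quantile normalization (0.0475), with a minimum of 2 FPKM (0.0489) and with no filter (0.0249). Without control replicate 2, 5 of its genes fell and 3 rose, and without fatty acid replicate 1 or 2 only 1 fell. After rescaling to TPM 8 of its genes were higher, and with median-of-ratios scaling or quantile normalization none was. HNF4A and NR1D1 were not called without fatty acid replicate 1 (0.0552 and 0.0588) or 2 (0.052 and 0.0521), and NR5A2 was not called without control replicate 3 (0.0746) or fatty acid replicate 1, 2 or 3 (0.126, 0.114 and 0.099), nor with median-of-ratios scaling (0.0626), quantile normalization (0.054), scaling to nuclear reads (0.063), the replicate block (0.0525), no filter (0.103) or thinning (0.0505), or without the intensity trend (0.0604).

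A panel of 24 genes was fixed before the data were examined, of which 20 were tested. PLIN2, PDK4 and CPT1A rose, 12 drug metabolism, transport and regulator genes fell, and SLCO1B1, ABCB1, ABCC2, NR1H4 and PPARA did not pass. Adjusted over the list alone, 3 were higher and 15 lower. In addition to the genes above, UGT2B7, a glucuronosyltransferase acting on morphine, fell from 41.9 ± 2.33 to 20.1 ± 1.66 FPKM (limma adjusted p = 0.000299), the steroid sulfotransferase gene SULT2A1 from 76.1 ± 3.99 to 46.6 ± 1.10 FPKM (0.000434) and CYP2E1, which oxidizes ethanol, from 17.2 ± 0.805 to 13.5 ± 0.141 FPKM (0.0114). ABCC2, the canalicular conjugate exporter, had a log2 fold change of -0.05 ± 0.05 (0.601), NR1H4, the bile acid receptor FXR, of -0.12 ± 0.07 (0.313), PPARA of -0.18 ± 0.07 (0.138), SLCO1B1 of -0.29 ± 0.11 (0.129) and ABCB1 of -0.21 ± 0.06 (0.0569). CYP2C19, CYP2D6, ABCB11 and NR1I3 lay below the expression minimum, with 37, 23, 74 and 61 reads in the control libraries and 20, 13, 79 and 18 in the fatty acid libraries. These reads are not adjusted for the greater depth of the fatty acid libraries. Mean FPKM were 0.477, 0.341, 0.493 and 0.638 in controls and 0.177, 0.146, 0.398 and 0.138 with fatty acid. Only the groups of NR1I3 did not overlap, and none of these genes was tested. An exact permutation test of 3 against 3 cannot give a two-sided p below 0.1, and 18 panel genes reached that value. CYP2E1 and CPT1A were not called without fatty acid replicate 1 (adjusted p 0.0665 and 0.0555) or 2 (0.0576 and 0.0529), nor CYP2E1 after rescaling to TPM (log2 fold change -0.21, adjusted p 0.1). ABCB1 was called without control replicate 1 (0.0458) and with median-of-ratios scaling (0.0396), scaling to nuclear reads (0.0372), voom on recovered reads (0.0323) or a minimum of 2 FPKM (0.045), and SLCO1B1 without control replicate 2 (0.0431).

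**Figure D2:**
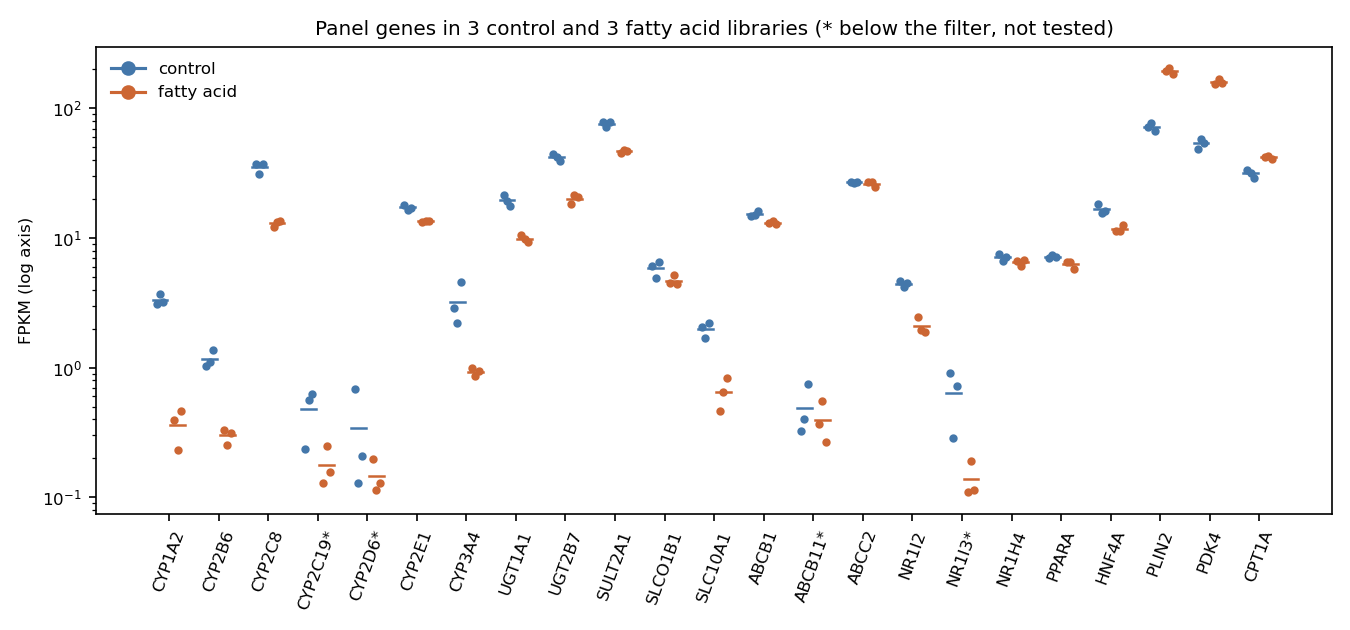
Points give FPKM on a log axis for each of 3 control and 3 fatty acid libraries, with a line at each group's mean, for 23 of the 24 panel genes. PLIN2 lies near 71.9 FPKM in controls and 194.3 FPKM with fatty acid, while CYP2C8 lies near 35.2 and 13.04 FPKM.

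The PPAR receptors bind fatty acids. Of 32 tested genes in the list of their targets, drawn up mainly outside fatty acid oxidation, 13 rose and 3 fell. Adjusted over the list alone 14 were higher and 6 lower. PDK4, which restrains pyruvate oxidation, rose from 53.7 ± 4.63 to 160.6 ± 8.29 FPKM, ANGPTL4 as above, and the lipid droplet coat gene PLIN2 from 71.9 ± 4.76 to 194.3 ± 10.1 FPKM (each limma adjusted p = 8.74e-05). The pantetheinase gene VNN1 rose from 72.1 ± 2.57 to 129.7 ± 2.84 FPKM, and the acyl-CoA synthetase gene ACSL1 from 186.3 ± 5.19 to 329.6 ± 8.05 FPKM (both 0.00014). The members that fell were CYP4A11, CYP8B1 and ETNK2. CYP4A11 is also in the fatty acid oxidation list, so its fall is counted in both. The set test passed with camera (adjusted p = 0.000425) and not with an estimated correlation (adjusted p = 0.0903).

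Fatty acid oxidation genes moved both ways. Of 44 tested genes, 7 rose and 6 fell, and adjusted over the list alone 7 were higher and 13 lower. HADHA and HADHB, the subunits of the mitochondrial trifunctional protein, rose with log2 fold changes of 0.57 ± 0.06 and 0.51 ± 0.05 (limma adjusted p = 0.00107 and 0.00167). The omega-hydroxylase genes CYP4A22 and CYP4A11 fell by 1.41 and 1.11 on the log2 scale (0.000299 and 0.000762), and the ketone body enzyme gene BDH1 fell from 2.08 ± 0.230 to 0.543 ± 0.0208 FPKM (0.00102). The list was lower than other genes by camera (adjusted p = 0.00981) and not with an estimated correlation (adjusted p = 0.272) or after rescaling to TPM (0.0601). The rising genes numbered 3 without fatty acid replicate 1 or 2, and the falling genes numbered 12 with median-of-ratios scaling, 10 with quantile normalization and 11 with scaling to nuclear reads.

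Of 24 lipid droplet and triglyceride genes tested, 4 rose and 4 fell (8 and 5 adjusted over the list alone). Beside PLIN2, the lysosomal lipase gene LIPA and PLIN4 rose by log2 fold changes of 0.49 ± 0.05 and 0.59 ± 0.07 (limma adjusted p = 0.00109 and 0.00323), and HSD17B13, which encodes a hepatocyte lipid droplet protein, fell from 2.91 ± 0.594 to 1.04 ± 0.219 FPKM (0.00644). The set did not pass (camera adjusted p = 0.988); its median of -0.02 and its mean of 0.03 differ in sign. Of 21 fatty acid synthesis genes, 3 rose and 7 fell (4 and 7 adjusted over the list alone), without a call for the set (camera adjusted p = 0.161). ELOVL5 and FADS1, which lengthen and desaturate polyunsaturated fatty acids, rose by 0.44 ± 0.05 and 0.39 ± 0.06 (0.00167 and 0.00712), while MLXIPL, the carbohydrate response factor ChREBP, had 85.7 ± 16.0 and 44.6 ± 9.08 FPKM (0.0164) and lost its call without control replicate 3 (0.0506) or fatty acid replicate 1 or 2 (0.0668 and 0.0533), or with no filter (0.0553). Of 27 cholesterol synthesis genes, 7 rose and 1 fell (10 and 3 adjusted over the list alone), led by SQLE with a log2 fold change of 0.33 ± 0.05 (0.00647). The set did not pass (camera adjusted p = 0.093), though it did without control replicate 1 (0.04) or 3 (0.0325), after rescaling to TPM (0.0312) and with no filter (0.0118). FDFT1, the squalene synthase gene, and TMEM97 followed at 0.30 ± 0.05 and 0.29 ± 0.06 (0.0104 and 0.0277); neither passed without fatty acid replicate 1 (0.0668 and 0.119) or 2 (0.0588 and 0.0965), nor TMEM97 without control replicate 2 (0.0517) or fatty acid replicate 3 (0.0736), with median-of-ratios scaling (0.072), quantile normalization (0.0796), scaling to nuclear reads (0.0727), thinning (0.0616) or no filter (0.0584), or without the intensity trend (0.0687).

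Several counts here moved with a library or the scaling. The falling droplet genes numbered 2 without control replicate 3 or fatty acid replicate 1 or 2, and the rising ones 8 after rescaling to TPM. The falling fatty acid synthesis genes numbered 3, 1, 1 and 3 without control replicate 3 and fatty acid replicates 1, 2 and 3. They numbered 2 after rescaling to TPM and 4 with no filter, and the rising ones numbered 5 without control replicate 1. The rising cholesterol genes numbered 3, 2, 2 and 3 without control replicate 2 and fatty acid replicates 1, 2 and 3, 3 with median-of-ratios scaling and 11 after rescaling to TPM. The falling cholesterol genes numbered 2 without control replicate 2, and none fell without control replicate 3 or any 1 fatty acid replicate.

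Of 14 bile acid genes tested, 7 fell and 2 rose (8 and 2 adjusted over the list alone). AKR1D1, the steroid 5-beta-reductase gene, fell from 3.96 ± 0.512 to 0.870 ± 0.144 FPKM (limma adjusted p = 0.000334) and BAAT, the bile acid conjugating enzyme gene, from 34.8 ± 1.00 to 22.3 ± 0.897 FPKM (0.00063). The set was lower (camera adjusted p = 2.37e-06, and adjusted p = 0.034 with an estimated correlation). Of 19 lipoprotein genes, 12 fell and 2 rose (13 and 2 adjusted over the list alone), with APOC3 from 816.2 ± 118.2 to 318.9 ± 11.8 FPKM (0.000332), APOC1 from 141.1 ± 12.01 to 81.0 ± 3.47 FPKM (0.00076) and APOA2 from 36.7 ± 1.69 to 24.0 ± 0.842 FPKM (0.000969), against the rise of APOA4. That set was lower too (camera adjusted p = 1.24e-05, and adjusted p = 0.0428 with an estimated correlation). Of 27 glucose metabolism genes, 9 fell and 2 rose (10 and 2 adjusted over the list alone). The glucose transporter gene SLC2A2 fell from 26.3 ± 0.0896 to 15.2 ± 0.359 FPKM (0.000176) and the glucose-6-phosphatase gene G6PC from 13.5 ± 1.34 to 5.997 ± 0.368 FPKM (0.000434), while IGFBP1, an insulin-repressed secreted protein, rose from 5.63 ± 0.414 to 11.9 ± 0.288 FPKM (0.000244). The camera call of the glucose list (adjusted p = 0.00517) was lost with an estimated correlation (adjusted p = 0.272). The falling lipoprotein genes numbered 6 and the falling glucose genes 5 without fatty acid replicate 1 or 2. With no filter the falling lipoprotein genes numbered 7. Without control replicate 3 or fatty acid replicate 1, 2 or 3 only 1 bile acid gene rose, and without any 1 of the 6 libraries only 1 glucose gene rose.

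Inflammation and acute-phase genes rose together. Of 31 tested genes, 20 rose and none fell (22 and 0 adjusted over the list alone). The chemokine gene CCL2 rose from 3.76 ± 0.192 to 10.8 ± 0.558 FPKM (limma adjusted p = 8.74e-05), CXCL1 from 20.6 ± 0.757 to 48.9 ± 5.90 FPKM (0.000294), and TNFAIP3, an inhibitor of NF-kappa-B signalling, from 7.80 ± 0.214 to 15.1 ± 0.718 FPKM (0.000229). SAA2, a serum amyloid gene whose reads may be shared with SAA1, rose from 308.4 ± 26.6 to 583.8 ± 7.82 FPKM (0.000347). The set was higher than other genes (camera adjusted p = 2.59e-12, and adjusted p = 0.0206 with an estimated correlation). Of 20 interferon response genes, 6 rose and none fell (the same counts adjusted over the list alone), among them IRF1 from 2.23 ± 0.0934 to 3.52 ± 0.209 FPKM (0.00739) and OAS3 from 3.49 ± 0.132 to 4.87 ± 0.0957 FPKM (0.00976), with IRF7 at a log2 fold change of 0.60 ± 0.11 (0.0141). The camera call of that list (adjusted p = 0.0191) was lost with an estimated correlation (adjusted p = 0.49), with fry (0.0503), with a minimum of 2 FPKM (0.121), and without control replicate 3 or fatty acid replicate 3 (0.0869 and 0.122). The rising interferon genes numbered 1, 1 and 3 without fatty acid replicate 1, 2 or 3, and OAS3 and IRF7 were not called without fatty acid replicate 1 (0.0588 and 0.0622) or 2 (0.0504 and 0.0691).

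Of 28 endoplasmic reticulum stress genes, 17 rose and none fell (19 and 0 adjusted over the list alone). The chaperone gene HSP90B1 rose from 271.4 ± 10.1 to 412.7 ± 14.2 FPKM (limma adjusted p = 0.000672), HSPA5, which encodes BiP, from 244.3 ± 7.22 to 360.1 ± 21.1 FPKM (0.00167), and PDIA6 and DNAJC3 by log2 fold changes of 0.51 ± 0.05 and 0.49 ± 0.05 (0.00102 and 0.00138). The set call (camera adjusted p = 7.19e-11) was lost with an estimated correlation (adjusted p = 0.0882). Of 28 oxidative stress genes, 8 rose and 1 fell (10 and 1 adjusted over the list alone). SOD2, the mitochondrial superoxide dismutase gene, rose from 90.8 ± 3.21 to 174.6 ± 5.43 FPKM (0.000106), the cystine transporter gene SLC7A11 from 2.42 ± 0.0634 to 5.64 ± 0.586 FPKM (0.000571), and the metallothionein genes MT1X and MT1E by 0.73 ± 0.08 and 0.56 ± 0.06 (0.00208 and 0.00218). This set call (camera adjusted p = 0.00405) was also lost with an estimated correlation (adjusted p = 0.274). Of 25 cell cycle genes, 12 rose and none fell (17 and 0 adjusted over the list alone), with TOP2A from 17.8 ± 0.242 to 27.8 ± 2.47 FPKM (0.00228), BUB1B at 0.56 ± 0.07 (0.00468), TPX2 at 0.48 ± 0.07 (0.00632) and RRM2 at 0.47 ± 0.07 (0.00934). Its call (camera adjusted p = 1.69e-07) was lost with an estimated correlation (adjusted p = 0.0882). The rising reticulum stress genes numbered 8 and 10 without fatty acid replicate 1 or 2, and the rising cell cycle genes 4 and 3. The rising cell cycle genes numbered 7 without control replicate 3 and 6 with no filter, and RRM2 was not called without fatty acid replicate 2 (0.0531). The 1 falling oxidative stress gene was not called without fatty acid replicate 1, 2 or 3, or with no filter.

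Hepatocyte markers fell, and the tested markers of the other cell types showed no matching rise. Only 12 of 21 biliary and progenitor markers and 11 of 19 mesenchymal and stellate markers were expressed highly enough to be tested. A rise among the others would not be seen in these counts. Of 24 hepatocyte markers, 17 fell and 1 rose (18 and 3 adjusted over the list alone). CPS1, the entry enzyme of the urea cycle, fell from 40.1 ± 0.428 to 13.3 ± 0.280 FPKM (limma adjusted p = 3.06e-05), the transthyretin gene TTR from 279.5 ± 17.5 to 115.7 ± 5.48 FPKM and the transferrin gene TF from 184.7 ± 6.24 to 89.1 ± 3.39 FPKM (both 8.74e-05), and AHSG, which encodes fetuin-A, from 24.6 ± 1.33 to 9.98 ± 0.680 FPKM (0.000135). The marker that rose was the fibrinogen gene FGB, which the inflammation list also holds. The set was lower (camera adjusted p = 3.12e-15, and adjusted p = 0.0206 with an estimated correlation). Of 12 biliary and progenitor markers, 1 fell, CD24, from 82.9 ± 2.52 to 64.5 ± 1.45 FPKM (0.00474), and none rose (the same counts adjusted over the list alone). That list passed with camera (adjusted p = 0.0411) and not with an estimated correlation (adjusted p = 0.153), after rescaling to TPM (0.116), without the intensity trend (0.0602), or without control replicate 2 (0.0594) or fatty acid replicate 1 or 2 (0.0625 and 0.0553), and 2 of its genes fell without control replicate 1; CD24 was not called after rescaling to TPM (0.0513). Of 11 mesenchymal and stellate markers, 1 rose, LUM, by 0.45 ± 0.07 (0.00846), and none fell (2 and 2 adjusted over the list alone), with no call for the set (camera adjusted p = 0.87) and a median of 0.06 and a mean of -0.04 that differ in sign. LUM was not called without fatty acid replicate 1 (0.0537); 2 mesenchymal genes rose without control replicate 2, and 1 fell without fatty acid replicate 3, and 3 rose after rescaling to TPM. Only 3 immune and endothelial markers could be tested, too few for a set test; KDR fell from 40.7 ± 3.48 to 25.6 ± 0.972 FPKM (0.00195), and 1 marker rose without control replicate 1. Of 23 extracellular matrix genes, 5 fell and 2 rose (9 and 6 adjusted over the list alone), without a set call (camera adjusted p = 0.184). CTGF and THBS1, matrix-associated genes, fell by 0.90 and 0.38 on the log2 scale (0.00527 and 0.00861), and MMP14 and LAMB1 had log2 fold changes of 0.30 ± 0.05 and 0.23 ± 0.05 (0.0114 and 0.0331). Without fatty acid replicate 1 or 2, MMP14 (0.0695 and 0.052) and LAMB1 (0.142 and 0.134) were not called, and no matrix gene rose. LAMB1 was not called without control replicate 2 or 3 (0.0513 and 0.0807) either, when 1 matrix gene rose, nor with median-of-ratios scaling (0.0622), quantile normalization (0.0724), scaling to nuclear reads (0.0571) or no filter (0.06), or without the intensity trend (0.0867). After rescaling to TPM, 8 matrix genes were higher and 3 lower. The falling matrix genes numbered 2, 3, 2 and 2 without control replicates 1 and 3 and fatty acid replicates 1 and 2.

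Transcripts of the mitochondrial genome were lower with fatty acid, close to the threshold. Of 13 tested genes, 4 fell (11 adjusted over the list alone) and none rose, with a median log2 fold change of -0.47. MT-ND4L had 8491 ± 359.6 and 5617 ± 748.1 FPKM (limma adjusted p = 0.013), MT-ND5 5041 ± 701.5 and 3586 ± 470.2 FPKM (0.0482), and MT-ND4 and MT-ATP6 log2 fold changes of -0.51 ± 0.14 and -0.49 ± 0.13 (0.0485 and 0.0487). The camera call (adjusted p = 4.2e-06) was lost with an estimated correlation (adjusted p = 0.274), with fry (0.0607) and with quantile normalization (0.0828), which moved the median to -0.06. The number of falling genes was 1, 1, 0, 1 and 10 without control replicates 2 and 3 and fatty acid replicates 1, 2 and 3. MT-ND5, MT-ND4 and MT-ATP6 were not called without control replicate 2 (0.104, 0.0955 and 0.0947) or 3 (0.115, 0.111 and 0.11) or fatty acid replicate 1 (0.161, 0.168 and 0.163) or 2 (0.158, 0.156 and 0.15). Without fatty acid replicate 1 MT-ND4L was not called (0.0633), nor MT-ATP6 without control replicate 1 (0.0513). All 4 calls were lost with no filter (MT-ND4L 0.308, MT-ND5 0.319, MT-ND4 0.53 and MT-ATP6 0.597) and with quantile normalization (0.27, 0.167, 0.994 and 0.0802), where the log2 fold change of MT-ND4L was -0.19. MT-ND5 and MT-ND4 were not called with median-of-ratios scaling (0.051 and 0.0504), and these and MT-ATP6 were not called without the intensity trend (0.0824, 0.0788 and 0.0767) or with scaling to nuclear reads (0.052, 0.052 and 0.0516). The median log2 fold change of the list was -0.519 with median-of-ratios scaling and -0.522 with scaling to nuclear reads. Voom on recovered reads called 11 of the 13 genes lower.

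**Figure D3:**
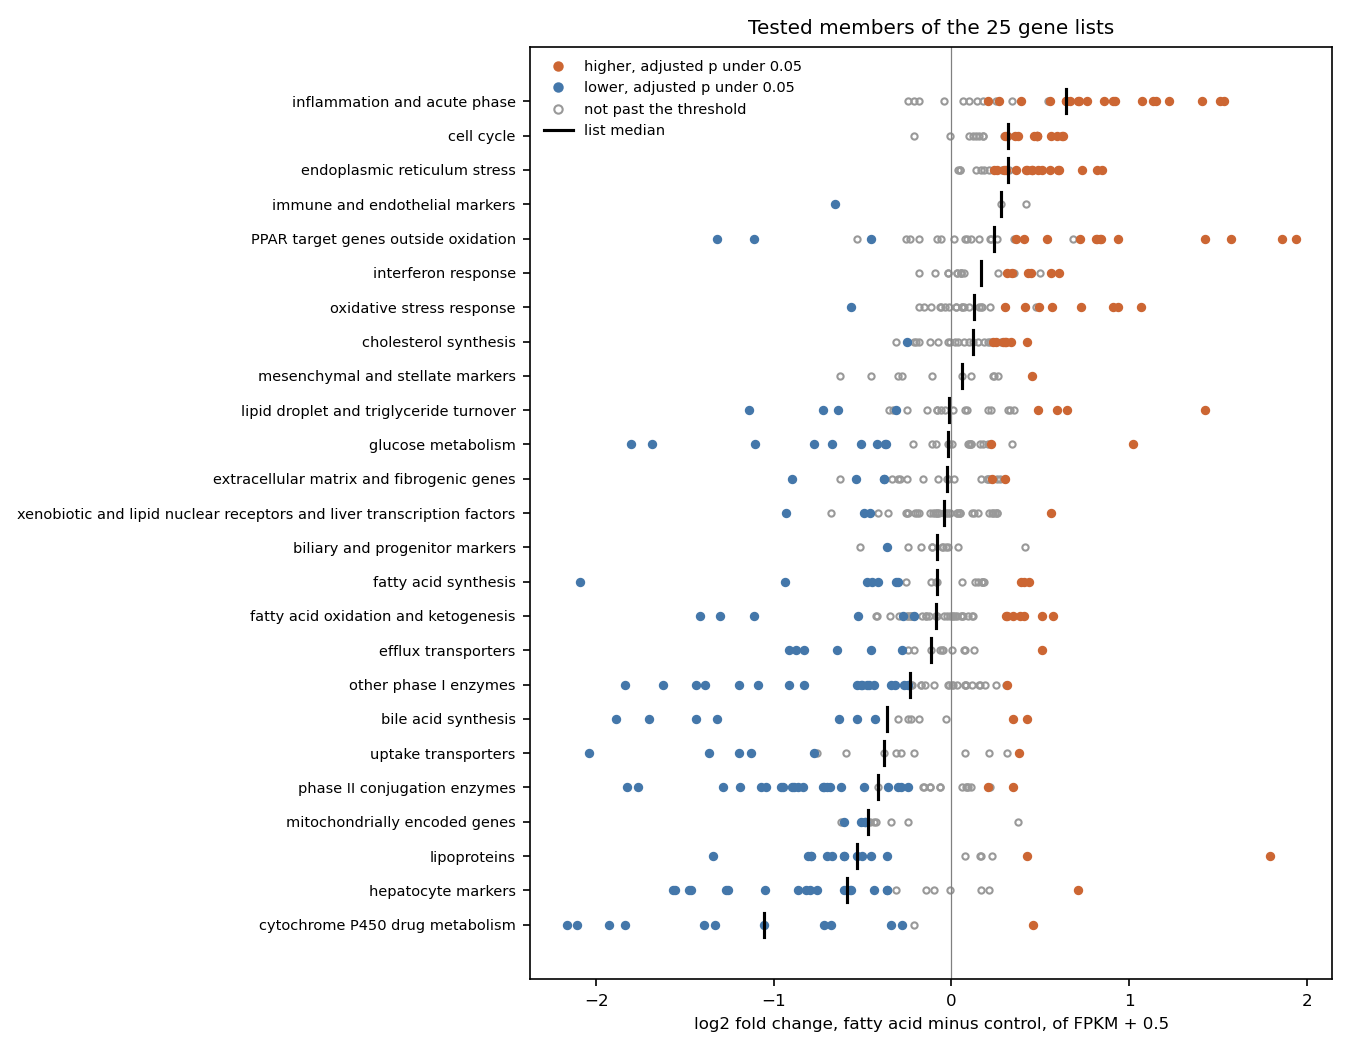
Each point is a tested gene of 1 of the 25 lists, placed by its log2 fold change of FPKM + 0.5 (fatty acid minus control), filled where the limma adjusted p was under 0.05, with a line at the list's median. The cytochrome P450 list has a median of -1.05 and the inflammation and acute-phase list a median of 0.64.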

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

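The test below was chosen after seeing the data. FGF21, a hormone gene induced by fasting and by PPAR-alpha (chromosome 19, 48755559 to 48758330), was among the genes left out by the minimum of 0.5 FPKM, so the report's gene test leaves it out (the setting with no filter takes it in), and its reads lay above the level of the controls. It had 0 reads in each control library and 6, 11 and 8 in the fatty acid libraries, 25 in all. That is at least 5.84-fold higher per read sequenced, with the floor set at 3 reads over the control group (95% exact lower limit 4.41, for counting error only). In a limma voom test of the 2934 genes under the minimum with 20 or more reads, its adjusted p was 0.0491. That test called 9 genes higher and 27 lower. Of those 9, FGF21 alone was protein-coding with a log2 fold change of at least 2 and groups that did not overlap. LIPE and IL1B, whose groups did not overlap either, had an adjusted p of 0.0805 and 0.0642 in it and did not pass. No explanation was tested for it.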

How the results depend on the processing

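Of the genes named by the rule and the lists fixed before the data were examined, none that passed the threshold turned to the opposite direction in its test under the alternatives run, and no called gene was called in the opposite direction. The voom test, the scaling to nuclear reads, the removal of genes under 200 bases and the thinning were chosen after seeing the data. In place of 1891 calls (1205 higher, 686 lower) there were 977 with no filter (640 and 337), 1101 without the intensity trend (642 higher), 3023 after rescaling to TPM (2615 and 408), 2999 with voom on recovered reads (1846 and 1153) and 137 with an absolute log2 fold change of at least 1 (39 and 98). The higher genes numbered 717 with median-of-ratios scaling, 758 with quantile normalization, 706 with scaling to nuclear reads and 803 after thinning. Of the 1891 genes, 932 were also called with no filter, 1037 without the trend, 1610 after rescaling to TPM and 1809 with voom. Leaving out 1 library gave 463 to 1629 calls (230 to 1109 higher, 233 to 686 lower), with fewer samples in each fit. The 68 drug metabolism and transport calls became 42 to 66 (2 to 7 higher, 40 to 59 lower) with 1 library left out, and 10 rather than 6 were higher after rescaling to TPM. The 15 panel calls became 11 to 16 with 1 library left out, and 0 in the exact permutation test, which cannot pass with 3 against 3. In place of 19 list calls there were 7 with an estimated correlation and 17 with fry, and 18 to 20 were made with 1 library left out. Among the single genes named by the rule, 113 results over all alternatives fell short of the threshold, 6 newly passed it and 1940 kept their side. Where no cause is given by the construction of the alternative, the cause was not tested.

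The sample titles give both groups the replicate numbers 1 to 3. The column headers, in contrast, number the samples serially, with no number shared between the groups. The replicate numbers of the titles are used below. The deviations of same-numbered libraries from their group means correlated at 0.012, 0.084 and 0.022, beside -0.094 to 0.073 for unlike numbers. Control replicate 1 and fatty acid replicate 3 correlated best with each other, and the other libraries with their own number. These values give no clear sign that the numbers pair the samples, and with 3 libraries per group they cannot exclude it. With the replicate block there were 1474 calls (817 higher, 657 lower). Settings set beforehand for a table of counts were not run, because the table holds FPKM. Depth limits low genes and short RNAs, such as MT-TN with 1 and 8 reads.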

Other observations

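The gene lists of this part were chosen only after the results were seen, as were the tests of the cell share, the scaling as a cause, the short RNAs and the receptor targets, the scaling to nuclear reads, the thinning and voom. Amino acid catabolism and urea cycle genes were lower: of 35 tested, 23 fell and 1 rose, KYNU (camera adjusted p = 3.71e-15, and adjusted p = 0.074 with an estimated correlation). Beside CPS1, the urea cycle genes ARG1 and OTC fell from 14.6 ± 2.00 to 4.92 ± 0.566 FPKM and from 6.36 ± 1.07 to 1.80 ± 0.193 FPKM (n = 3, limma adjusted p = 0.000403 and 0.000544), whereas ASS1 had 215.9 ± 13.4 and 242.2 ± 9.40 FPKM (0.113). The tyrosine-degrading enzyme gene TAT fell from 3.93 ± 0.367 to 1.11 ± 0.230 FPKM (0.000674). Coagulation genes were lower too, 11 of 18 with none higher (camera adjusted p = 8.31e-12, and adjusted p = 0.0222 with an estimated correlation), led by the kininogen gene KNG1, from 115.1 ± 2.14 to 58.9 ± 1.81 FPKM (8.74e-05). Of 22 complement genes, which hepatocytes also make, 1 rose and 2 fell (camera adjusted p = 0.921; their median of 0.06 and the direction of the test, lower, differ in sign).

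Of 28 NF-kappa-B targets, several of them also in the inflammation list, 16 rose and none fell (camera adjusted p = 6.71e-12, and adjusted p = 0.0281 with an estimated correlation). The list holds TNFAIP6, PTX3 and LCN2 of the largest rises, and SOD2, CCL2, CXCL1 and TNFAIP3 named above. Its set test thus partly restates results already seen. BIRC3, an inhibitor of apoptosis, rose from 26.2 ± 1.74 to 44.8 ± 1.52 FPKM (limma adjusted p = 0.000546). Metallothionein genes rose in 4 of 5 cases (camera adjusted p = 9.72e-05, and adjusted p = 0.131 with an estimated correlation). Smaller shifts appeared in 57 cytosolic ribosomal protein genes (7 higher, none lower, median log2 fold change 0.14, camera adjusted p = 8.03e-06), 31 proteasome genes (5 higher, none lower, 0.00213), 28 autophagy and lysosome genes (6 higher, none lower, 0.0205) and 23 apoptosis genes (3 higher, 1 lower, 0.0485). With an estimated correlation these 4 had adjusted p of 0.327, 0.351, 0.394 and 0.175, and the ribosomal median fell to 0.08 with scaling to nuclear reads. Among genes under the expression minimum, picked after their reads were seen, LIPE, the hormone-sensitive lipase gene, had 4 reads in controls and 56 with fatty acid, a depth-adjusted ratio of 9.82 (95% exact interval 3.63 to 37.3), and IL1B had 9 and 58 reads, a ratio of 4.52 (2.22 to 10.4). Both intervals cover counting error only. Neither gene passed in the limma voom test of genes under the minimum (adjusted p 0.0805 and 0.0642). GSTP1, ME1, UCP2, EPCAM and TNF were listed at 0 in every library. Whether such a 0 means no expression or reads that were not counted cannot be told from the FPKM values.

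Metabolic genes of hepatocytes fell while acute-phase genes, which hepatocytes make in the liver, rose. The libraries hold mixed cells, so which cells made these transcripts was not tested. If the hepatocyte-like cells made them, a lower share of these cells as the whole cause is argued against by the 18 liver-made acute-phase genes. Their median log2 fold change was 0.33 (quartiles 0.07 and 0.66, with 9 higher and none lower). Hepatocyte markers had -0.59 and the tested biliary markers -0.08. Some of these acute-phase genes had been seen to rise before, so the test largely restates the pattern itself. A smaller share together with a rise within the remaining cells was not tested and is not excluded. Scaling by the mitochondrial read share is argued against by the size of its effect. Scaling to nuclear reads applies the same factor to all genes of a library, so the direction of the move followed from the mitochondrial shares alone. It moved the log2 fold changes of the 13 tested P450 genes by a median of -0.047 (-0.054 to -0.029), away from 0, beside their median of -1.05. A candidate explanation is an acute-phase response of the hepatocyte-like cells, tested on acute-phase genes that had not been looked at: 14 known to rise had a median of 0.20 (5 higher, 3 lower) and 12 known to fall a median of -0.51 (8 lower, none higher), a difference of 0.71, above the 95th percentile of 0.20 of 10000 random pairs of lists matched on expression. HRG was taken out of the falling list after a first run of this test, because its value had been seen before. Some of the remaining falling genes are also in the coagulation list above, and some of the rising genes in the complement list. The test is therefore not separate from those results. The random pairs were matched on expression and not on hepatocyte origin. Hepatocyte markers had a median of -0.59, so a falling list of hepatocyte genes could pass this comparison without an acute-phase response. The acute-phase response remains a hypothesis. The falling genes are hepatocyte genes that a smaller hepatocyte share would lower too, and AGT, PLA2G2A and C4BPB of the rising list fell. The rising list alone had a camera adjusted p of 0.0405 (adjusted p = 0.28 with an estimated correlation).

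More genes were called higher than lower, 63.7% of the calls. Depth is argued against as the cause, because thinning every library to the shallowest left 62.4% higher (61.6% to 63.4% over 10 thinnings). Scaled to nuclear reads, 46% of the calls were higher, but median-of-ratios scaling gave 45.4% and quantile normalization 49.5%. The share of higher calls thus also fell under scalings that do not use the mitochondrial reads as such. Scaling to nuclear reads moved the median log2 fold change of all genes from 0.044 to -0.003, and median-of-ratios scaling moved it to 0. Each of these applies 1 factor per library and moved that median by a similar amount, so the calls cannot tell them apart. The shift of the median was of the size that the lower mitochondrial share gives. Whether that share is the cause of the excess of higher calls stays open. Whether the lower share of mitochondrial transcripts is itself a response to fatty acid was not tested.

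Very short RNAs stood among the largest fold changes. The 11 called genes under 200 bases had a median of 6 reads over all 6 libraries (4 to 108), against 3070 for all called genes, and voom on recovered reads called 4 of the 11. These values are consistent with few reads behind each large fold change, and no biological explanation was tested.

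CYP1A1 and CYP1A2, classical targets of the aryl hydrocarbon receptor, were among the largest falls. Lower receptor activity could lower them, but the 8 other targets had a median log2 fold change of 0.14 and went both ways (-0.51 to 0.46): ALDH3A1 and UGT1A6 fell and CYP1B1 rose. The median lay above the bound set against this explanation (-0.25 with at least 1 target higher), but members called both ways decide nothing, so the question stays open.

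Mitochondrially encoded transcripts had a median log2 fold change of -0.47. If there were fewer mitochondria, nuclear-encoded respiratory chain genes might fall too; 60 such genes had a median of -0.067 (quartiles -0.169 and 0.022), with 2 lower and none higher. This met the bound set beforehand against the explanation, a median above -0.1, though by less than the spread of the genes. The median was -0.121 with scaling to nuclear reads, -0.119 with median-of-ratios scaling, -0.12 with quantile normalization and 0.069 after rescaling to TPM, so the question stays open (camera adjusted p = 0.00213, and adjusted p = 0.351 with an estimated correlation).

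The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes, 1 of the 10 splits, the real one, reached its 1891 calls, and the highest other gave 3. For drug metabolism and transport genes the real split gave 68, reached by 1 of 10, and the highest other 0. For gene lists the real split gave 19, reached by 1 of 10, and the highest other 12. The 9 other splits gave 4 to 12 list calls at the preset correlation beside 0 to 3 gene calls. They mix both groups unevenly on each side, so part of the treatment difference stays in the contrast and the rest adds to the spread. Low gene counts in them follow in part from this construction.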
